A study of Mus musculus with 2 samples.

How the data were processed

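Open chromatin was profiled by the assay for transposase-accessible chromatin with sequencing (ATAC-seq) in neural tube of mouse embryos of strain B6NCrl at day 15.5 of gestation (E15.5). ATAC-seq inserts sequencing adapters into DNA that is accessible to the Tn5 transposase, and positions with many insertions are called as peaks. The series holds 1 group of 2 biological replicates. Per the labels, replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62, of mixed sex, and fragments were 200 to 750 bp long. There is no control tissue, second age or treatment, so no comparison between conditions was possible.

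The authors deposited peak lists on build mm10. The lists of 1 replicate were derived from that library's filtered alignments and the lists of the series from the alignments of both libraries, per the file headers and the accompanying notes; for some lists a further input file is named there without a description. Aligner, peak caller, their versions, any shift of reads for the transposase and the thresholds are not given in the sources used here. The signal value of each peak is the enrichment over a background as the authors' peak caller gave it, in the deposited narrowPeak column order. The p-value and q-value of each peak are deposited on a −log10 scale. The score of the deposited ranked lists is −log10 of the global irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats between 2 lists. Both scales were read from the column order and checked against the values. The signal value and the p-value are the authors' own values per peak and were used to describe or rank peaks within 1 list. Signal values were also correlated between the replicates' lists over shared regions, and for some regions the replicates' values are printed beside those of the conservative list. No read counts were used here, so the depth of each library in reads is unknown, and a difference in list length between replicates cannot be separated from a difference in depth.

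The list used for the main results was the conservative IDR-thresholded list of the series, which holds peaks reproducible between the 2 replicates. Each replicate's own IDR-thresholded list was set beside it to give the spread (mean ± SD, n = 2). These replicate lists were made within 1 library each, so they are measurements of single libraries. Below, a region or count given for a replicate refers to its own IDR-thresholded list. A region missing from that list may lie below its threshold, so signal need not be missing from the library. One interval can carry several summits in these lists. Intervals that shared a position were merged into 1 region, which was placed by its strongest summit. Columns of per-sample values without a sample numbered 0.

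Genes came from the GENCODE annotation of the same build (release 21 of the mouse set in the reference used here), with 21911 protein-coding genes and 54308 transcription start sites (TSSs). A region was called a promoter region when its strongest summit lay within 1 kb of a protein-coding TSS. Otherwise it was called exonic, intronic or intergenic in that order. Only protein-coding genes were used, so a region at another kind of gene could count as intergenic. A gene had a promoter region when a region came within 1 kb of any of its TSSs. Regions away from these promoters are called distal below, which can include starts of genes that do not code for protein. Each was assigned to the protein-coding gene with the nearest TSS within 500 kb. Nearness does not show that a region acts on that gene.

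The following choices were made before the data were examined: the 19 gene lists, the 20 motif consensus strings, the tests and the alternatives. The gene lists held 337 symbols, of which 325 were distinct, so some lists share members (Pax6, Slc1a3, Fabp7, Olig2, Nkx2-2, Isl1, Sox10, Foxd3, Prph, Runx1 and Tal1 among them). All symbols were found, Drgx under its synonym Prrxl1. Named genes followed a rule. In each list these were the 3 members with the highest promoter signal among those with a promoter region in both replicates, the member with most distal regions, and the first members in list order, up to a pair, without a promoter region in either replicate. Genome-wide, the 10 genes with most distal regions and the 5 regions with the highest signal were named. Other genes that are named below, such as the few members of a list that did or did not have a region, were chosen after their values were seen.

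Overlap between replicates was counted for regions sharing at least 1 bp, with 100 circular shifts of 1 list within chromosomes as the background. The shares carry 95% Clopper-Pearson intervals, which cover counting error only. Overlap and merging were done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 and gave the same counts as bedtools 2.31.1 for 20761 merged regions and 13705 shared regions of replicate 1. Promoter regions per list were tested with Fisher's exact test, two-sided, against all other protein-coding genes (scipy 1.17.1). Distal regions per list were compared with 10000 random lists of the same size, matched on the decile of each gene's territory, which is the stretch of genome nearest to its TSSs. These two-sided permutation p-values cannot be smaller than 0.0002 before adjustment. Motif matches on either strand were counted in windows of 201 bp centred on distal summits and in a window 2 kb away that overlapped no peak of the looser replicated list, and were compared by an exact McNemar test on the pairs. In the GC-matched alternative, each summit window was paired with a flank of any region within 2 points of its GC content. Flanks could be drawn repeatedly, so these pairs were not independent and their p-values may be too small. For the shuffled-consensus alternative, summit matches were compared by an exact binomial test with the mean share of matches to 20 shuffled strings. All p-values were adjusted by Benjamini-Hochberg over the 19 lists or the 20 motifs, with a threshold of 0.05. Genes and regions are not independent replicates, so these tests describe the 2 libraries and not the variation among animals. The columns used in place of a fold were the signal values described above.

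The code was tested on simulated data. Among simulated promoter lists of 16 genes, 80.5% were called when 95% of members had a region, 91.5% when 10% had one, and 0 of 200 at the background share. Distal lists of 16 genes with 4 times the regions were found in 60.0% of 200 simulations at an unadjusted p, and unchanged lists in 3.5%. With a CTCF consensus planted in 400 windows, 401 windows matched, while 0 of the 19 other motifs were called. Simulated summit windows and flanks had the same GC content, unlike the real ones. This simulation therefore cannot show how often a difference in GC content leads to a call.

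Alternatives were other deposited lists, the higher-signal part of each list, each replicate's list alone, other overlap rules, other promoter windows, 1 TSS per gene, random lists matched on promoter CpG content, other assignments of distal regions, random lists without territory matching, every summit as the unit, shorter motif windows, flanks matched on GC content and shuffled consensus strings. CpG content here means the ratio of observed to expected CpG in 1001 bp around the outer start of each gene, matched by decile. CpG-matched lists were not matched on the number of TSSs per gene. CpG matching was not combined with 1 TSS per gene. Second copies of a sequence were searched with blastn 2.17.0 against mm10, requiring at least 90% identity over at least 80% of the interval. Figures were drawn with matplotlib. Ranked lists were left out of the comparisons, since they hold peaks on both sides of the threshold, and the one behind the conservative list was used in the closing section alone.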

Results

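Accessible chromatin was measured by ATAC-seq in the neural tube of E15.5 mouse embryos, in 2 biological replicates made from pools of 78 and 62 embryos. The conservative list, made of peaks reproducible between the replicates, held 66763 summits in 21890 regions on build mm10. These regions had a median width of 1095 bp and covered 23.61 Mb. Replicate 1 alone gave 20761 regions and replicate 2 alone 14392. The depth of the libraries in reads is unknown, and with 1 library on each side there is no test of a difference between the replicates.

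The regions of replicate 2 were almost a subset of those of replicate 1. Of the 14392 regions of replicate 2, 13867 (96.4%, 95% interval 96.0 to 96.7) overlapped a region of replicate 1. In the other direction 13705 of 20761 regions (66.0%, 65.4 to 66.7) overlapped. After circular shifts of the other list, the overlap was 1.62% ± 0.105 and 1.13% ± 0.0677 (SD, n = 100 shifts). Across the 13705 shared regions the signal values of the replicates had a Spearman correlation of 0.904, which was 0.911 over 10253 promoter regions and 0.8 over 3452 distal regions. These correlations are across regions of 1 pair of libraries, and regions are not independent replicates. When the same number of highest-signal regions was taken from both lists, 81.4% of those of replicate 1 and 82.6% of those of replicate 2 were shared.

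Regions called in 1 replicate only were weaker, narrower and more often distal than shared regions. Replicate 1 had 7056 of them (34.0%) with a median signal of 5.75 and a median width of 710 bp, against 9.57 and 1192 bp in its shared regions, and 22.8% were promoter regions against 74.8%. Replicate 2 had 525 (3.65%) with 5.12 and 485 bp against 8.36 and 1022 bp, and 18.9% were promoter regions against 74.7%. Most were present in the other replicate below its IDR threshold. In replicate 1, 5856 (83.0%) overlapped the looser list of replicate 2, which left 1200 regions, or 5.78% of the list. For replicate 2 the looser list of replicate 1 left 38 regions, or 0.264%. No test was made of these values.

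Accessible regions concentrated at gene starts. Of the 21890 regions, 11983 (54.7%, 54.1 to 55.4) had their strongest summit within 1 kb of a protein-coding TSS, against 2.55% ± 0.135 (SD, n = 100) after shifting. Introns held 17.2% against 35.0% after shifting, intergenic sequence 25.5% against 59.3%, and exons 2.65% against 3.12%. Promoter regions had a median signal of 9.45 and a median width of 1276 bp, while intronic regions had 5.36 and 759 bp and intergenic regions 5.94 and 829 bp. The promoter share depended on how strict the list was. It was 57.2% in replicate 1 and 72.7% in replicate 2 (64.9% ± 11, SD, n = 2), 26.2% in the looser replicated list and 77.8% in the higher-signal part of the conservative list.

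A promoter region was found at 12449 of 21911 protein-coding genes (56.8%), with 12311 in replicate 1 and 11093 in replicate 2. Of 1134 olfactory receptor genes, which are used by sensory neurons of the nose, 2 (0.176%), Olfr9 and Olfr94, had a promoter region, and both were named after their values were seen. The looser replicated list held 9 of them.

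Genes used by neurons in general had open promoters. A promoter region was present at 16 of 17 pan-neuronal genes (94.1%), and each replicate's own list also held 16. The strongest were Syt1, a calcium sensor of synaptic vesicles, with a signal of 16.4 at chromosome 10, 109010187 to 109011795 (replicates 17.0 and 15.0), Scg3, a secretory granule protein, with 15.9 at chromosome 9, 75683515 to 75684617, and the synaptic adhesion gene Nrxn1 with 15.7. The region of Nrxn1, at chromosome 17, 90088054 to 90089016, lay at a start inside the gene. These signals stood at percentiles 95.2, 93.5 and 93.0 of all genes with a promoter region, whereas the median member stood at 25.6. Dcx, a microtubule-binding protein of migrating neurons, lacked a promoter region in the conservative list and in replicate 2 but had one in replicate 1, and Rbfox3 lacked one in replicate 1. The share was higher than among all other genes (adjusted p = 0.00654, Fisher's exact test) and than in random lists matched on promoter CpG content (65.9%, adjusted p = 0.00434, permutation test). In the higher-signal part of the list it was 47.1% (adjusted p = 0.809, Fisher's exact test).

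Genes of neural progenitors also had promoter regions more often than other genes, at lower signal. Of 16 members, 14 (87.5%) had one (adjusted p = 0.041, Fisher's exact test), 15 in replicate 1 and 10 in replicate 2. The strongest were at Vim, an intermediate filament of radial glia (8.21, chromosome 2, 13573317 to 13575130), Hes1, an effector of Notch signalling (6.85, chromosome 16, 30063128 to 30064544), and Sox2, a factor that maintains progenitors (6.52, chromosome 3, 34649233 to 34650667). The median member stood at percentile 8.05 of promoter signal. Nes and the proneural gene Neurog1 had no promoter region, and Neurog1 had none in either replicate. The call depended on the comparison: the share was 78.9% in random lists matched on CpG content (adjusted p = 0.642, permutation test), 62.5% in replicate 2 alone (adjusted p = 0.455, Fisher's exact test), 81.2% with either other promoter window and 75% with 1 TSS per gene, none of which passed. In the higher-signal part of the list the share was 6.25%, lower than in other genes (adjusted p = 0.00355, Fisher's exact test).

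Housekeeping genes served as a reference for open promoters. A promoter region was present at 14 of 15 (93.3%, adjusted p = 0.00882, Fisher's exact test), 15 in replicate 1 and 14 in replicate 2, with Ubc as the member without one in the conservative list. The highest signals were 14.8 at B2m, 14.0 at Rplp0 and 13.3 at Sdha, whose region also lay within 1 kb of a start of Ccdc127. The median member stood at percentile 61.4. Against the 77.5% of CpG-matched lists the share did not pass the permutation test (adjusted p = 0.172), and it was 80% with 1 TSS per gene (adjusted p = 0.115, Fisher's exact test).

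**Figure D1:**
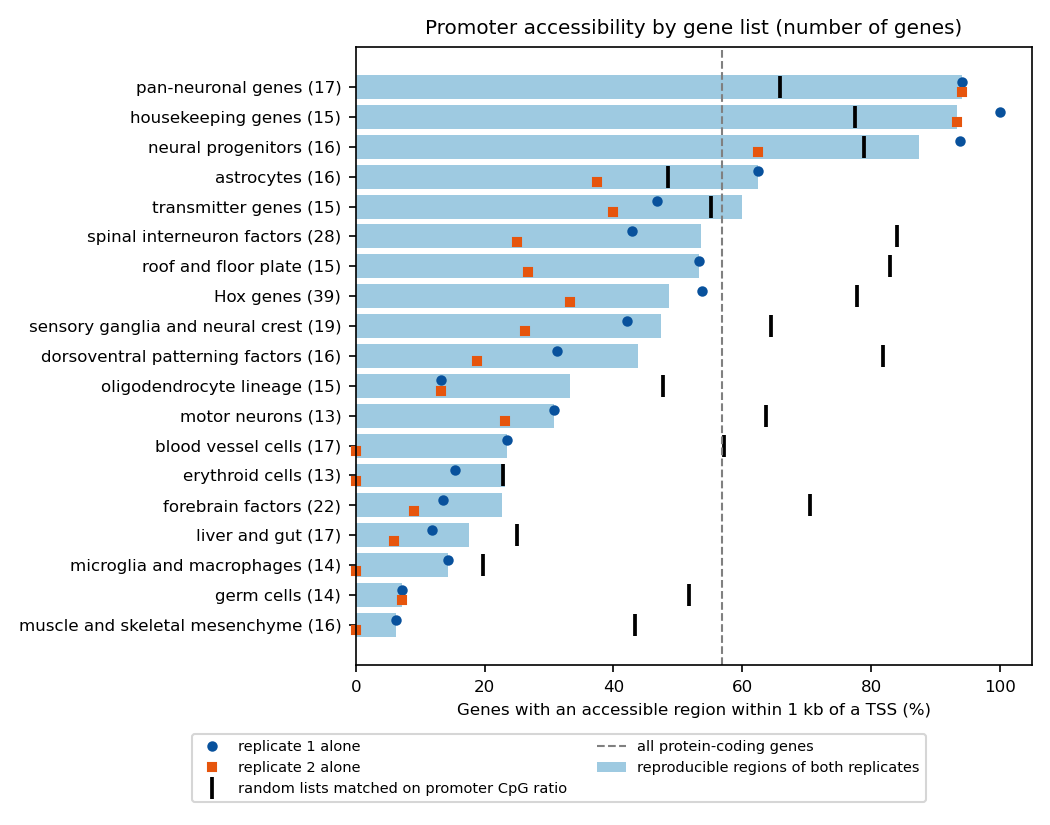
Percent of the members of each of 19 gene lists that had a promoter region: bars show the list from both replicates, points the single replicates, ticks the mean of CpG-matched random lists, and the dashed line all protein-coding genes (56.8%). Pan-neuronal and housekeeping genes lie highest (94.1% and 93.3%) and muscle and skeletal mesenchyme lowest (6.25%).

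Markers of tissues and cell types outside the neural lineage rarely had promoter regions. Among muscle and skeletal mesenchyme genes 1 of 16 (6.25%) had one, at Runx2, a regulator of bone formation, and the myogenic factors Myod1 and Myf5 had none in either replicate (adjusted p = 0.000609, Fisher's exact test). Of 14 germ cell genes only Dazl, an RNA-binding protein of germ cells, had one (7.14%, adjusted p = 0.00144, Fisher's exact test), and its signal of 13.3 at chromosome 17, 50292594 to 50293673 was at percentile 79.5, while Ddx4 and Sycp1 had none. Among 17 liver and gut genes 3 had one (17.6%, adjusted p = 0.00654, Fisher's exact test), namely Apoa1, Apob and Lgr5, a receptor of intestinal stem cells (7.34, chromosome 10, 115586873 to 115588193), and Alb and Afp, which encode secreted proteins of liver, had none in either replicate. The region of Apob, with a signal of 4.87, was in neither replicate's own list.

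Markers of blood and of vessels also rarely had promoter regions. Of 17 genes of blood vessel cells 4 had a promoter region (23.5%, adjusted p = 0.0156, Fisher's exact test), at Cldn5, Erg, Esam and Kcnj8, and the endothelial adhesion genes Pecam1 and Cdh5 had none. Of 14 microglia and macrophage genes 2 had one (14.3%, adjusted p = 0.00654, Fisher's exact test), at C1qc and Runx1, and the receptors Csf1r and Cx3cr1 had none. Of 13 erythroid genes 3 had one (23.1%, adjusted p = 0.041, Fisher's exact test), at Klf1, Gypa and Tal1, and Gata1 and the globin gene Hbb-bs had none in either replicate. No member of these lists had a promoter region in replicate 2 alone, against 4, 2 and 2 in replicate 1. Lists matched on CpG content reached 19.7% for microglia, 22.9% for erythroid cells and 25.1% for liver and gut, and against these none of the 3 lists passed the permutation test (adjusted p = 0.961, 1.0 and 0.756). Muscle and skeletal mesenchyme, germ cells and blood vessel cells did (43.3%, 51.8% and 57.1%, adjusted p = 0.0019, 0.00095 and 0.00591, permutation test). In the looser replicated list blood vessel cells (52.9%), muscle and skeletal mesenchyme (50%) and erythroid cells (30.8%) no longer passed Fisher's exact test (adjusted p = 0.566, 0.477 and 0.0526), and with 1 TSS per gene erythroid cells did not (23.1%, adjusted p = 0.0991, Fisher's exact test).

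Forebrain transcription factors also had promoter regions less often than other genes. A promoter region was present at 5 of 22 (22.7%, adjusted p = 0.00654, Fisher's exact test), with 13.6% in replicate 1 and 9.09% in replicate 2. The 5 were at Dlx6, Lhx8, Satb2, Bcl11b and Neurod6, a factor of cortical projection neurons (7.36, chromosome 6, 55680958 to 55681611). The telencephalic genes Foxg1 and Emx1 had none in either replicate. CpG-matched lists reached 70.5% (adjusted p = 0.00095, permutation test). In the looser replicated list 68.2% of the forebrain factors had a region, above the background and not past the test (adjusted p = 0.871, Fisher's exact test).

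Genes that pattern the spinal cord, and those of motor neurons, had promoter regions less often than random lists matched on promoter CpG content. The random lists were not matched on the number of TSSs per gene. Against all other genes the 4 gene lists did not pass the test. Of 16 dorsoventral patterning factors 7 had one (43.8%, adjusted p = 0.453, Fisher's exact test), the strongest at Irx5 (9.19, chromosome 8, 92355644 to 92356800) and Prdm8 (8.95), followed by Pax6 (5.68), whose region lay at a start inside the gene. The region of Irx5 lay upstream of the gene, which starts at 92357625, and came within 1 kb of a TSS without covering one. Olig2 and Nkx2-2, factors of ventral progenitors, had none in either replicate. Among 28 spinal interneuron factors 15 had one (53.6%, adjusted p = 0.896, Fisher's exact test), the strongest at Sim1 (9.28, chromosome 10, 50894214 to 50895364), Lhx1 (7.33) and Lhx5 (6.83). Barhl1, a factor of dorsal interneurons, had none, and Lmx1b had one of signal 3.37 that was in neither replicate's own list. In the roof and floor plate list 8 of 15 had one (53.3%, adjusted p = 0.896, Fisher's exact test), led by the signalling gene Bmp6 (8.85), the ciliary factor Foxj1 (7.95) and Arx (6.71), and Lmx1a and Wnt1, genes of the roof plate, had none. Of 13 motor neuron genes 4 had one (30.8%, adjusted p = 0.142, Fisher's exact test), at Isl1, Ret, Foxp1 (6.97, at a start inside the gene) and Etv4 (8.7), and Isl2 and Mnx1 had none. CpG-matched lists reached 81.8%, 84.0%, 83.0% and 63.7% for these lists in the order given, and all 4 were lower than their matched lists (adjusted p = 0.00152, 0.00095, 0.016 and 0.0057, permutation test). In replicate 2 alone the dorsoventral and interneuron lists were also lower than other genes (18.8% and 25%, adjusted p = 0.0186 and 0.0129, Fisher's exact test). In the looser replicated list 75%, 82.1%, 66.7% and 92.3% of the 4 lists had a promoter region.

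Genes of neurotransmission, of glia and of the sensory ganglia did not pass the test against other genes in the conservative list. Of 15 transmitter genes 9 had a promoter region (60.0%, adjusted p = 1.0, Fisher's exact test), with the highest signals at the glutamate receptor Gria2 (9.04), the GABA transporter Slc6a1 (8.9) and the GABA receptor Gabra2 (8.19). The region of Gad1, which makes GABA, had a signal of 2.98 and was in neither replicate's own list, and the glycine transporter Slc6a5 had none. Of 16 astrocyte genes 10 had one (62.5%, adjusted p = 0.896, Fisher's exact test), led by Nfia (8.88), Aldoc (7.55) and Slc1a2 (6.67), while Gfap and Aqp4, which are markers of mature astrocytes, had none in either replicate. Of 15 oligodendrocyte lineage genes 5 had one (33.3%, adjusted p = 0.126, Fisher's exact test), at Olig1 (7.09), Sox8, Pdgfra, Mbp and Cnp. Sox10, like Olig2, had none in either replicate. This list was lower than other genes in each replicate's own list (13.3% in both, adjusted p = 0.00267 and 0.00716, Fisher's exact test). Of 19 genes of sensory ganglia and neural crest 9 had one (47.4%, adjusted p = 0.619, Fisher's exact test), the strongest at Mpz (12.6), in a region that also lay within 1 kb of a start of Sdhc, then Scn9a (9.25) and Pou4f1 (7.97), whereas Ntrk1 and Six1 had none. Against CpG-matched lists these 4 lists did not pass either (55.2%, 48.5%, 47.7% and 64.4%, adjusted p = 0.961, 0.364, 0.308 and 0.172, permutation test).

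In the conservative list, the Hox genes, which encode position along the body axis, had promoter regions only in paralog groups 1 to 10, and not at all genes there. Of 39 genes 19 had a promoter region (48.7%), 21 in replicate 1 and 13 in replicate 2. All 19 were among the 30 genes of paralog groups 1 to 10, and 0 of the 9 genes of groups 11 to 13 had one in the conservative list or in either replicate. The looser replicated list held a promoter region at 27 of the 30 and 4 of the 9. The strongest were at Hoxc10 (6.84, chromosome 15, 102966302 to 102967379), Hoxa1 (6.74, chromosome 6, 52157959 to 52159448) and Hoxa4 (6.27, chromosome 6, 52191793 to 52192480), and the median member stood at percentile 6.44. Hoxa2 and Hoxa5 had none in either replicate, nor had Hoxb1. Hoxc6, Hoxc8 and Hoxc9 had none in the conservative list. Regions were present at 6 of 11 genes of HoxA, 6 of 10 of HoxB, 3 of 9 of HoxC and 4 of 9 of HoxD. The whole list did not pass against other genes (adjusted p = 0.453, Fisher's exact test) and was lower than CpG-matched lists (77.8%, adjusted p = 0.00095, permutation test). The division by paralog group was made after the data were seen and was not tested.

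**Figure D2:**
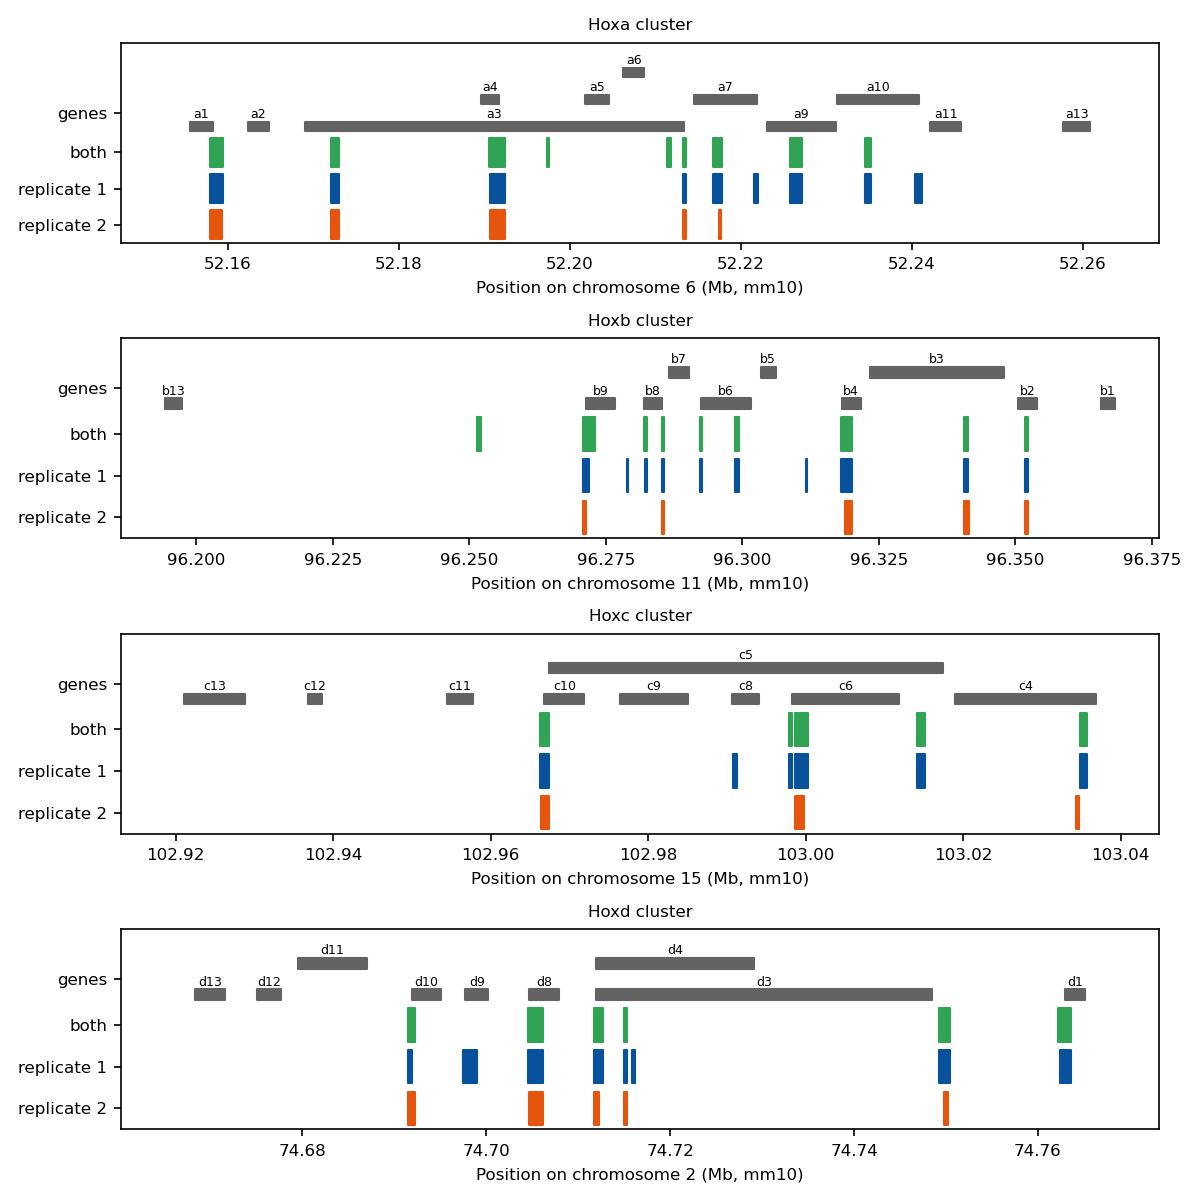
Maps of the 4 Hox clusters on mm10 with position on the horizontal axis, genes as grey bars, and accessible regions of the list from both replicates and of each replicate as bars. The 9 genes of paralog groups 11 to 13 have no promoter region in any of the 3 lists.

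Distal regions gathered around progenitor and astrocyte genes. Neural progenitor genes had a mean of 2.62 distal regions, 3.13 times the 0.838 of random lists matched on territory (adjusted p = 0.0038, permutation test). Sox2 and Sox9 had 6 each, Hes1, Pax6 and Ascl1 5 each, and 4 of the 16 members none. The counts differed between the replicates' own lists, with 4 and 1 for Sox2, 9 and 2 for Sox9 and 4 and 2 for Hes1. They were 1 and 1 for Pax6 and 4 and 4 for Ascl1. Of the regions of Sox2 or Pax6, 0 were in the own lists of both replicates. The strongest region of Sox2 was intergenic, at chromosome 3, 35088270 to 35089390 (signal 5.88), 438 kb from its TSS. It was not in the own list of replicate 2. Astrocyte genes had a mean of 2.19, 2.91 times the 0.752 of matched lists (adjusted p = 0.0171, permutation test). Nfia, a factor of glial differentiation, had 7, all intronic, the strongest at chromosome 4, 97868284 to 97869486 (signal 8.67), and Nfib had 6. In the replicates' own lists Nfia had 10 and 2 and Nfib 8 and 2, and 2 of the 7 regions of Nfia were in both lists. Fabp7 and Slc1a3 are in both lists. The ratios in the replicates were 3.14 and 3.59 for progenitors (3.37 ± 0.319, SD, n = 2) and 3.88 and 2.9 for astrocytes (3.39 ± 0.694). Replicate 1 alone passed for both lists (adjusted p = 0.0019, permutation test), and replicate 2 alone for neither (adjusted p = 0.0722 and 0.151). In the higher-signal part of the list the ratios were 1.59 and 1.06 (adjusted p = 1.0, permutation test).

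The other 17 lists did not pass. Oligodendrocyte lineage genes had a ratio of 2.42 (adjusted p = 0.212, permutation test), with 2 regions at Olig1. Hox genes had 2.22 (adjusted p = 0.327) and passed in the looser replicated list with 3.24 and when regions in the gene body and 20 kb around it were counted with 3.61 (adjusted p = 0.0038 and 0.0019, permutation test). Housekeeping genes stood at 2.08, with 3 regions at Eef1a1, erythroid cells at 1.78, pan-neuronal genes at 1.65, with 7 regions at Nrxn1 and 6 at Gap43, muscle and skeletal mesenchyme at 1.52, with 4 regions at Matn1, and microglia at 1.33. Of the 4 regions assigned to Ptprc in the microglia list, the strongest had a signal of 10.7 and lay 277 kb from its TSS. Spinal interneuron factors and transmitter genes stood at 1.31, dorsoventral patterning factors at 1.27, the roof and floor plate list at 1.22 and sensory ganglia and neural crest at 1.01. Liver and gut (0.83), motor neurons (0.745), blood vessel cells (0.612), forebrain factors (0.573) and germ cells (0.197) had fewer regions than matched lists, which did not pass. Some ratios departed from these in replicates 1 and 2: transmitter genes turned to 0.911 and 0.878, germ cells had 0.44 and 0.484, motor neurons 0.589 and 0.282, liver and gut 0.462 and 0.679, microglia 2.07 and 1.4, erythroid cells 1.61 and 0.0 and housekeeping genes 2.66 and 4.02. None of the 17 lists passed in either replicate. Adjusted p-values of the lists without a p here ranged from 0.414 to 0.956 (permutation test). Lmx1a, which had no promoter region, had 4 distal regions, Lmx1b 5 and Slc6a5 4. Counts of most of these genes were lower in 1 or both replicates: 1 and 0 for Olig1 and for Matn1, 7 and 3 for Nrxn1, 6 and 3 for Gap43, 6 and 3 for Ptprc, 3 and 2 for Lmx1a, 3 and 3 for Lmx1b and 2 and 1 for Slc6a5, against 3 and 3 for Eef1a1. None of the regions of Olig1, Matn1 or Slc6a5 was in the own lists of both replicates. Only the member with most distal regions in each list was compared for its strongest distal region. Among these genes, the strongest was in an intron of the neurotrophin receptor Ntrk2, at chromosome 13, 59040210 to 59041760, with a signal of 15.1 (replicates 15.2 and 13.3).

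**Figure D3:**
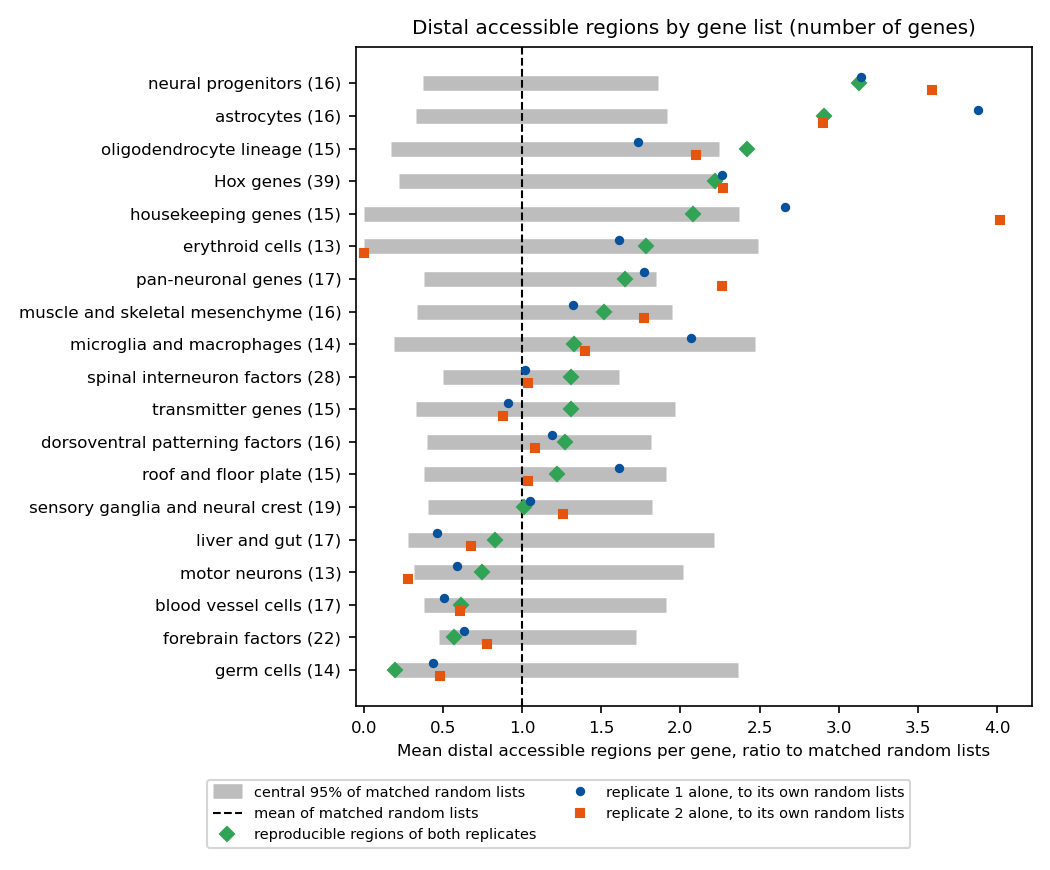
Ratio of the mean number of distal regions per gene to that of random lists matched on territory, for 19 gene lists, with the central 95% of random lists in grey and single replicates as points. Neural progenitors (3.13) and astrocytes (2.91) are the lists that passed the permutation test.

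Across the genome, Tmem161b and Ubash3b had most distal regions in the conservative list, with 20 each. Myt1l, a neuronal zinc finger factor, had 16, Mef2c, a factor of neurons and muscle, 15 and Rapgef5 13. Gm11146, Sorl1, Zfp516 and Zmiz1 had 12 each and Auts2 11. The mean over all protein-coding genes was 0.443, and 16315 genes had none. The strongest distal region of Myt1l was intergenic at chromosome 12, 29290322 to 29291478 (signal 15.0), 237 kb from its TSS, and 8 of its 16 regions were in both replicates. That of Ubash3b had a signal of 12 at chromosome 9, 41273033 to 41274390, and 9 of its 20 were in both replicates. For Tmem161b, whose neighbour on chromosome 13 is Mef2c, 19 of 20 were intergenic and 6 were in both replicates, with the strongest at 84448472 to 84449960 (signal 12). The order depended on the list. In replicates 1 and 2 Tmem161b had 11 and 7, Ubash3b 18 and 10, Myt1l 12 and 10, Mef2c 9 and 12, Gm11146 12 and 9 and Rapgef5 10 and 4, and in the looser replicated list Rapgef5 had 43 and Tmem161b 26. No test was made of these counts.

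The 5 regions with the highest signal were narrow, intergenic and present in both replicates. The highest had a signal of 55.2 in 245 bp at chromosome X, 143482936 to 143483180, 35.5 kb from a TSS of Pak3. The next, also with the distance to a TSS, were at chromosome 2, 69355471 to 69355735 (49.7, 13 kb from Abcb11), chromosome 2, 3964420 to 3964690 (37.8, 53.2 kb from Frmd4a), chromosome 5, 60042765 to 60043105 (34.9, 1770 kb from G6pd2) and chromosome 10, 96077549 to 96077951 (32.7, 58.9 kb from Gm5426). Each of the last pair had a match to mitochondrial DNA, and the region on chromosome 5 also had a second copy on a chromosome, a limit on placing reads there.

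Distal summits were rich in the site of CTCF, a factor that organises chromatin loops. Its motif lay in 8.26% of 9893 distal windows against 0.131% of flanks, 62.8 times as often (adjusted p = 2.59e-223, exact McNemar test), and in 7.99% and 6.63% of the windows of replicates 1 and 2 (7.31% ± 0.962, SD, n = 2). Flanks held it in 0.0338% and 0.204% in the replicates, so the size of the ratio was not stable. RFX motifs, bound by factors of ciliary genes, lay in 7.19% against 1.43%, 5.04 times as often (adjusted p = 1.31e-93, exact McNemar test). The E-box of proneural factors lay in 33.7% against 23.8% (1.42 times, adjusted p = 1.77e-53), the SOX motif in 7.65% against 5.85% (1.31 times, adjusted p = 1.18e-06) and the POU octamer in 1.96% against 1.22% (1.6 times, adjusted p = 7.79e-05), all by the exact McNemar test. The POU octamer did not pass in the higher-signal part of the list (a difference of 0.783 points, adjusted p = 0.0565, exact McNemar test). The homeodomain motif lay in 6.2% against 5.38% (1.15 times, adjusted p = 0.0241, exact McNemar test). The call depended on the setting. The difference passed in the looser replicated list (2.26 points) and in the other IDR-thresholded list (0.991), with adjusted p = 3.11e-39 and 0.00215 by the exact McNemar test. Against shuffled forms of the consensus the difference was 1.04 points and also passed (adjusted p = 1.09e-05, exact binomial test). It did not pass in the other cases with unmatched flanks, where it was -1.32 points in the higher-signal part of the list, -0.408 in replicate 2 alone, 0.439 in replicate 1 alone and -0.0707 in shorter windows (adjusted p = 0.0565, 0.627, 0.312 and 0.932, exact McNemar test).

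Motifs that are common at promoters were also more frequent at distal summits than in flanks. Distal summits could include starts of genes that do not code for protein, which were not set apart. SP/KLF sites lay in 3.88% against 0.516% (7.53 times, adjusted p = 2.05e-65), the cyclic AMP response element CRE in 1.0% against 0.152% (6.6 times, adjusted p = 7.85e-16), ETS sites in 0.799% against 0.182% (4.39 times, adjusted p = 6.8e-10) and YY1 sites in 0.364% against 0.162% (2.25 times, adjusted p = 0.0142), all by the exact McNemar test. NRF1 sites lay in 33 summit windows and 0 flanks, at least 11-fold more often against a floor of 3 windows (adjusted p = 6.65e-10, exact McNemar test). The ratios of ETS and YY1 were larger in the single replicates, where ETS lay in 0.81% and 1.38% of windows against 0.09% and 0.204% of flanks and YY1 in 0.461% and 0.459% against 0.09% and 0.128%. For ETS the difference from shuffled forms of its own consensus was -0.0096 points, so that call was lost there. In promoter windows SP/KLF sites reached 20.4% and ETS sites 7.49%, while CTCF sites were at 0.893%. The GATA motif, read by factors of blood and of some interneurons, was less frequent at summits than in flanks (1.1% against 2.68%, 0.411 times, adjusted p = 7.51e-16, exact McNemar test).

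Summit windows had 53.8% GC and flanks 45.0%, and matching on GC content moved several ratios. Matched flanks came from any region and could be reused, so the p-values against them may be too small. SP/KLF stood at 2.39 in place of 7.53 and CRE at 3.31 in place of 6.6, both still past the test, and YY1 was at 0.897 and no longer passed (adjusted p = 0.758, exact McNemar test). The proneural E-box lay in 33.8% against 28.2% of matched flanks, a ratio of 1.2 in place of 1.42 (adjusted p = 6.8e-17, exact McNemar test). The homeodomain motif stood at 3.33 and the POU octamer at 3.13 against matched flanks (adjusted p = 2.36e-58 and 1.26e-16, exact McNemar test). MEF2 motifs did not pass against unmatched flanks in the main list (0.495% against 0.313%, adjusted p = 0.0872) and did against matched flanks (4.08 times, adjusted p = 3.28e-06, exact McNemar test). With unmatched flanks they passed as higher in the looser replicated list (0.12 points, adjusted p = 0.01) and as lower in the higher-signal part of the list (-0.412 points, adjusted p = 0.0355, exact McNemar test). PU.1, AP-1, TEAD, NFI, REST, nuclear receptor DR1 and HNF1 motifs did not pass against unmatched flanks in the main list. Of these, NFI passed as higher in the looser replicated list and the other IDR-thresholded list (adjusted p = 9.03e-07 and 0.0481), REST as higher and DR1 as lower in the replicated list (adjusted p = 0.0281 and 0.0255), and AP-1 as lower in the higher-signal part of the list (adjusted p = 0.0289), all by the exact McNemar test. PU.1, a factor of macrophages, lay in 1.04% against 1.26% (0.824 times, adjusted p = 0.229, exact McNemar test) and AP-1 in 3.43% against 3.44% (adjusted p = 1.0, exact McNemar test), and both were lower against matched flanks (0.669 and 0.847 times, adjusted p = 0.00271 and 0.034, exact McNemar test). Against shuffled forms of its own consensus, PU.1 passed in the other direction, as higher at summits. TEAD lay in 3.18% against 3.17%, NFI in 3 windows against 0, REST in 2 against 2, DR1 in 1 against 3, and HNF1 in 0 against 0.

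**Figure D4:**
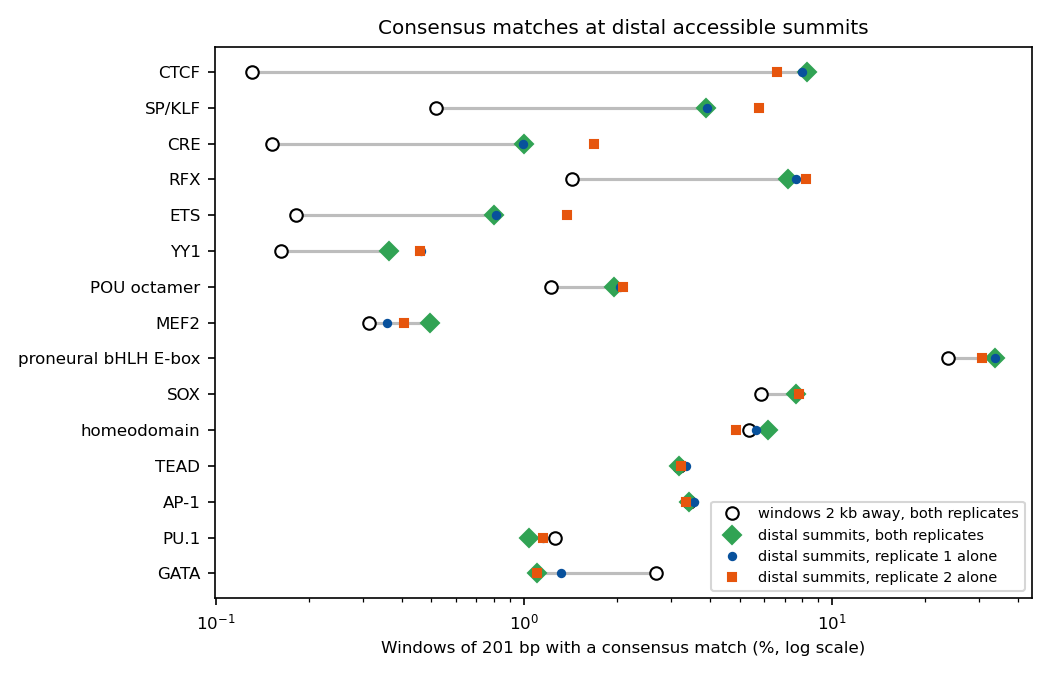
Percent of windows with a match, on a log axis, for 15 motifs with matches at distal summits and in flanks, in the list from both replicates and in each replicate. CTCF shows the largest ratio of summits to flanks among these motifs (8.26% against 0.131%), and GATA lies below its flanks (1.1% against 2.68%).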

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

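The test in this part was chosen after the left-out intervals had been seen, and the outcomes that would count for and against it were set down before the search for copies was run.

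A signal appeared in data that the comparisons did not use. In the ranked list behind the conservative list 66934 of 128117 summits passed an IDR of 0.05, and the conservative list held 66763 of them. The threshold is not given in the sources used here and was inferred from the comparison of these lists, so the counts of what was left out depend on it. The remaining 171 summits lay in 64 intervals. Of the 20 intervals with the highest −log10 p in the ranked list, 5 were among those left out, and the first was at chromosome 1, 24611586 to 24616165, with a −log10 p of 5718.

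Of the 171 summits, 51 lay on 10 unplaced or unlocalized sequences, while the conservative list held regions on 21 chromosomes. The step that left the summits out is not given in the sources used here. A candidate explanation for the 45 intervals on chromosomes is sequence present in several copies of the genome or in mitochondrial DNA. The interval on chromosome 1 matched mitochondrial DNA. Those next by −log10 p had no second match, on chromosome 6 (103648978 to 103649356) and chromosome 2 (98666170 to 98667341 and 98662445 to 98662923). A second match was found for 18 of the 45 (40.0%, 95% interval 25.7 to 55.7), against 0 of 200 random regions (up to 1.83%). The random regions were not matched on width, which limits the comparison. The median was 1095 bp over all conservative regions and 648.5 bp over all left-out intervals. The share with a second match lay between the at least 50% set down for copies as the cause and the 1.83% set down against it. Copies may therefore account for part of the intervals and the rest stays open, in part because copies missing from the assembly would not be found. Repeats that cover less than 80% of an interval, or that overlap the interval itself, were not counted either. An interval without a second match need not be unique sequence. No biological explanation was tested, since the series has 1 group.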

How the results depend on the processing

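All alternatives below were set down before the data were examined, except that the shuffled-consensus comparison was given a floor of 1 match after its first values were seen. For every value that moved, lost its call or turned, the cause was not tested. The depth in reads is unknown, so it cannot be said which losses in replicate 2 come from depth. No paired analysis was possible because the series has 1 group. Pan-neuronal genes passed Fisher's exact test or the permutation test in 8 of 9 alternatives, germ cells in 9 of 9, and CTCF, RFX, E-box, SOX, SP/KLF, CRE, NRF1 and GATA motifs kept their direction and call in all 8. Of 171 values of promoter shares under alternatives 121 kept direction and call, 17 newly passed, 14 no longer passed and 19 turned. For distal ratios 140 of 171 kept both, and for motifs 130 of 160. Distal and promoter results for single named genes were counts without a test, of which 161 of 250 and 35 of 544 moved.

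Without replicate 1 or replicate 2, that is with the other replicate's own list, the number of regions was 14392 to 20761, the promoter share 57.2% to 72.7%, exons 1.9% to 2.5%, introns 8.92% to 15.6% and intergenic sequence 16.5% to 24.7%. Promoter shares ranged from 62.5% to 93.8% for neural progenitors, 37.5% to 62.5% for astrocytes and 40.0% to 46.7% for transmitter genes. Distal ratios ranged from 3.14 to 3.59 for neural progenitors, 2.9 to 3.88 for astrocytes, 0.0 to 1.61 for erythroid cells and 0.878 to 0.911 for transmitter genes, and 0 to 2 lists passed as higher. Motif differences ranged from -0.408 to 0.439 points for the homeodomain, from -0.204 to 0.113 for TEAD and from -0.714 to 0.0338 for AP-1.

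The overlap of replicate 1 and replicate 2 regions (66.0% and 96.4%) was 62.4% and 90% with a reciprocal overlap of 50%, 64.9% and 94.9% with a summit within 100 bp, 57.2% and 84.4% with the pseudoreplicated lists, 68.2% and 98.5% in the higher-signal part of each list and 81.4% and 82.6% with lists of equal length. Regions called in 1 replicate only were 37.6% and 10.0% with the reciprocal overlap and 5.78% and 0.264% against the other replicate's pseudoreplicated list.

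With the replicated list there were 57671 regions, of which 26.2% were promoter regions, 3.63% exonic, 33.6% intronic and 36.6% intergenic. The lists with a lower promoter share numbered 3 in place of 7: blood vessel cells (52.9%), erythroid cells (30.8%) and muscle and skeletal mesenchyme (50%) no longer passed, and forebrain factors (68.2%) turned. Uncalled lists that turned were Hox genes (79.5%), dorsoventral patterning factors (75%), motor neurons (92.3%), roof and floor plate (66.7%), sensory ganglia (73.7%) and spinal interneuron factors (82.1%). Distal ratios turned for erythroid cells (0.68), liver and gut (1.12) and motor neurons (1.01), AP-1 turned (0.263 points), MEF2 newly passed as higher (0.12 points), and 2 motifs were lower in place of 1. The other IDR-thresholded list turned Hox genes (59.0%), roof and floor plate (60.0%), transmitter genes (53.3%), the distal ratio of sensory ganglia (0.985) and AP-1 (0.0438 points), none of which passed.

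In the higher-signal part of the conservative list 77.8% were promoter regions, 1.21% exonic, 5.84% intronic and 15.1% intergenic. Lists with a lower promoter share numbered 16 and those with a higher share 1. Neural progenitors turned to 6.25% (adjusted p = 0.00355, Fisher's exact test), astrocytes to 12.5% (adjusted p = 0.0222, Fisher's exact test) and transmitter genes to 26.7%, which did not pass, and pan-neuronal genes lost their call at 47.1%. For distal regions 0 lists passed: neural progenitors had a ratio of 1.59 and astrocytes 1.06. Ratios turned for Hox genes and erythroid cells (0.0 each), dorsoventral patterning factors (0.568), liver and gut (1.11), microglia (0.755), roof and floor plate (0.64), spinal interneuron factors (0.326) and transmitter genes (0.345). The POU octamer (0.783 points) no longer passed, the homeodomain (-1.32), MEF2 (-0.412, now passing as lower) and TEAD (-0.494) turned, and 3 motifs were lower.

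Promoter definitions changed the call of neural progenitors. These genes stood at 81.2% with 500 bp either side and with 2 kb upstream to 500 bp downstream, where exons held 3.3% and 3.11% of regions. With 1 TSS per gene, neural progenitors (75%), housekeeping genes (80%) and erythroid cells (23.1%) lost their calls, 1 list was higher, and astrocytes (43.8%) and transmitter genes (53.3%) turned. Against CpG-matched lists 1 list was higher: housekeeping genes (93.3%), neural progenitors (87.5%), liver and gut (17.6%) and microglia (14.3%) lost their calls, and erythroid cells (23.1%) lay above their matched mean.

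Without territory matching 4 lists had more distal regions, and the ratios of Hox genes (0.576), blood vessel cells (1.07), erythroid cells (0.866), forebrain factors (1.23) and motor neurons (1.22) turned. Counting regions in the gene body and 20 kb around it turned erythroid cells (0.757) and liver and gut (1.09), and a limit of 100 kb turned sensory ganglia (0.752). None of these passed. Hox genes newly passed with the gene body and 20 kb (3.61, adjusted p = 0.0019, permutation test).

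For motifs, flanks matched on GC content turned YY1 (-0.0407 points) and gave 3 lower motifs. Shorter windows turned the homeodomain (-0.0707), AP-1 (0.243) and TEAD (-0.141). Shuffled consensus strings turned ETS (-0.0096), AP-1 (0.345), NFI (-0.00505), PU.1 (0.218, now passing as higher) and the DR1 site (0.00758), and TEAD (1.59) and REST (0.0202) newly passed as higher there.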

Other observations

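The descriptions in the next 3 paragraphs were chosen after the values were seen, although the replicated list was an alternative set down beforehand, and both tests that follow them were set down before their results were seen.

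Most gene lists, neural and non-neural, had weak promoter regions, and in many lists more members had one in the looser replicated list. Among genes with a promoter region in the conservative list, the median signal stood at percentile 15.7 for dorsoventral patterning factors, 7.6 for spinal interneuron factors, 15.6 for motor neurons, 18.3 for the roof and floor plate, 16.4 for transmitter genes, 12.4 for astrocytes, 5.81 for the oligodendrocyte lineage, 9.54 for sensory ganglia and neural crest and 3.27 for forebrain factors. Lists outside the nervous system were also low, at 3.6 for blood vessel cells, 6.44 for microglia and macrophages, 7.32 for erythroid cells and 14.0 for muscle and skeletal mesenchyme, from 1 to 4 genes each. Liver and gut stood at 25.2 (3 genes), close to pan-neuronal genes at 25.6, while the 1 germ cell gene stood at 79.5 and housekeeping genes at 61.4. No test of signal was made. In the replicated list, where 63.6% of all protein-coding genes had a promoter region, 16 of 16 neural progenitor genes, 12 of 13 motor neuron genes, 23 of 28 spinal interneuron factors, 12 of 16 dorsoventral patterning factors, 31 of 39 Hox genes and 15 of 22 forebrain factors had one. Of these 6 lists only neural progenitors passed Fisher's exact test there (adjusted p = 0.00491, against 0.0919 for motor neurons, interneuron factors and Hox genes, 0.566 for dorsoventral patterning factors and 0.871 for forebrain factors). Muscle and skeletal mesenchyme rose to 8 of 16 from 1 and blood vessel cells to 9 of 17 from 4. Germ cell genes (1 of 14), liver and gut genes (3 of 17) and microglia and macrophage genes (4 of 14) had few, with adjusted p = 0.000344, 0.00133 and 0.0318 by Fisher's exact test. The replicated list also held 33 distal regions for Sox2 and 19 for Hes1, against 6 and 5 in the conservative list.

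Promoter and distal windows differed in the motifs they held. The proneural E-box lay in 16.3% of 11983 promoter windows and 33.7% of 9893 distal windows, the SOX motif in 3.3% and 7.65%, and the homeodomain motif in 0.693% and 6.2%. The opposite held for ETS (7.49% and 0.799%), YY1 (2.86% and 0.364%), CRE (3.53% and 1.0%) and NRF1 (1.74% and 0.334%). RFX lay in 4.39% and 7.19%. Promoter and distal windows were not matched on GC content, so differences in base composition may enter these shares. No test was made of them.

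The sex chromosomes held 637 regions on X and 8 on Y in the conservative list, from pools of mixed sex.

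Some summits of the IDR-thresholded lists had little signal of their own. The conservative list held 5351 summits (8.01%) with a −log10 p from 2 to 5. A candidate explanation is that a weak summit takes the rank of its interval. In the ranked list 82.8% of 6143 such summits passed an IDR of 0.05, a threshold inferred from the lists, where the interval also held a summit with a −log10 p of 20 or more, against 28 of 3713 (0.754%) where the summit was alone, a difference of 82.0 points when at least 20 had been set down for this explanation. Counting merged regions placed by their strongest summit, as was done here, gives them little weight, since 29 of the 21890 regions held such summits alone, and no biological explanation was tested.

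The regions with the highest signal were examined for repeated sequence. Of the 20 highest, 11 were intergenic and 8 were promoter regions, and all 20 were in both replicates. A candidate explanation of such signal is sequence present in several copies of the genome or in mitochondrial DNA. A second match was found for 6 of the 20 (30.0%, 95% interval 11.9 to 54.3), including 3 with a match to mitochondrial DNA, against 0 of 200 random regions (up to 1.83%). The random regions were not matched on width, which limits the comparison: the median was 1095 bp over all regions and 765 bp over the 20 highest. The count of 6 lay between the at least 10 set down for copies as the cause and the upper bound of random regions. Copies may therefore account for these 6 and the others stay open, the 3 highest regions among them. Repeats that cover less than 80% of a region, or that overlap the region itself, were not counted. No biological explanation was tested, since the series has 1 group.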
